A study of Homo sapiens with 9 samples.

How the data were processed

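The 9 libraries of LAPC4 cells were analysed, 3 per treatment, and each library was assigned to its group and replicate number from the submitters' labels. The authors deposited whole-number counts of reads per gene for each library, not normalized, for 58735 genes. RNA was made into libraries with a NEBNext Ultra kit and read as pairs, per the labels' protocols. The submitters' processing notes name fastp, STAR, DESeq2 and the genome build GRCh38.p12, without roles or versions. The counting tool, its strand setting and the annotation release were not given in the sources used here. Reads from a gene and an antisense or overlapping partner can therefore not be told apart, and near-identical gene copies may share or lose reads. All 58735 identifiers matched GENCODE release 29 on GRCh38, which gave symbols, gene types and coordinates.

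Totals per library were 15834105 to 18623197 counts, at which a count of 0 allows a level of up to 0.161 to 0.189 CPM, from 3 counts and for counting error only. Pairs of libraries within a group differed far beyond sampling noise (chi-square per degree of freedom 14.7 to 39.4), so none was counted as a duplicate.

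Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14498, and libraries were scaled by TMM. All 9 libraries entered 1 robust quasi-likelihood fit with a mean per group and 6 residual degrees of freedom, and each pair of groups was tested with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are given with standard errors, and levels as TMM-scaled CPM with the SD over 3 libraries. Each standard error was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. A list of genes was tested against the other genes with camera at a preset correlation of 0.01, again with the correlation estimated, and with fry, which tests whether a list's genes move one way on balance. The 31 lists held 619 gene entries, all matched, and list p-values were adjusted over the lists of a comparison.

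The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names BAG1 and AR always. It then names up to 10 protein-coding genes with the largest rise and 10 with the largest fall among those past the threshold, with a mean of at least 1 CPM over the libraries compared and no overlap between the groups. It further names up to 4 members with the smallest adjusted p of each list described, and for both compounds together the genes changed the same way or in opposite directions. A list is described if camera passed it, if 3 members passed, or if it holds BAG family, androgen-responsive or cell type genes. Because few genes passed without the block, the same rule was also applied to the fit with the replicate block, a choice made after the data were seen, as were the list members named because that fit called them.

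The replicate numbers come from the labels, which do not say what a number stands for. Deviations from the group means correlated at 0.379 to 0.617 between same-numbered libraries and at -0.472 to -0.005 between differently numbered libraries of different groups, and 9 of 9 libraries correlated best with their own number. Deviations cancel out within a group, so positive values for same-numbered libraries push the others to be negative. The negative range is therefore no separate evidence of pairing. Since every same-number correlation was over 0.1, the numbers were taken to pair the libraries, and a fit with the number as a block, with 4 residual degrees of freedom, is given beside the fit without it where it changes a call.

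The procedure was tested on simulated counts for the 14498 genes with 200 changed genes. Means, replicate effects and spread were taken from the blocked fit, so a gain from the block was built in. Genes were drawn independently in a single draw per comparison, and changed genes were taken from those with higher counts. For A4B17 against vehicle, it recovered 25.4% of genes changed by 1.5-fold, 65.7% by 2-fold and 95.5% by 4-fold without the block, with 0 false calls among 124. With the block it recovered 74.6%, 88.1% and 100%, with 17 false calls among 192. For enzalutamide against vehicle, false calls were 0 of 121 without and 10 of 190 with the block.

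Alternatives were other scalings, other filters on low counts, DESeq2, limma-voom, fits of only the groups compared, the block with and without a correction for GC content and gene length, stricter thresholds, and leaving out each library in turn. The block was also run with DESeq2 and limma-voom, and the alternatives were repeated within the blocked fit, after the data were seen. Correlations between the comparisons that share vehicle libraries were set against 40 simulated draws of unchanged groups.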

Results

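RNA sequencing gene counts were analysed from cells that the labels name LAPC4, an established androgen-receptor-positive human prostate cancer cell line. Cells were grown for 48 h in medium with 10% serum and 1 nM of the androgen dihydrotestosterone, then exposed for 16 h to vehicle (DMSO), to 5 µM A4B17, which the labels call an inhibitor of BAG1L, or to 5 µM enzalutamide, an antagonist of the androgen receptor (AR). BAG1L is the long protein form made from BAG1, a co-chaperone gene, and gene counts do not separate it from the shorter forms. Each group had 3 libraries, with total counts from 15834105 to 18623197 per library. Between 19884 and 22683 genes had at least 1 count in a library, and 14498 genes with enough counts were tested. EEF1A1, a translation elongation factor gene, held the largest share of counts in every library, 1.26% to 1.54%. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

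Libraries that carried the same replicate number resembled each other more than libraries of the same treatment did. The number accounted for 55.5% of the variance over the tested genes and the treatment for 19.04%. These are raw shares that noise between libraries also fills, so 19.04% does not measure the size of a treatment effect. The libraries numbered 2 had counts in 19884 to 20173 genes, against 21566 to 22683 in the other libraries, and in all 3 treatments. For this reason, values from a fit with the replicate number as a block are given beside the fit without it wherever they change a call.

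**Figure D1:**
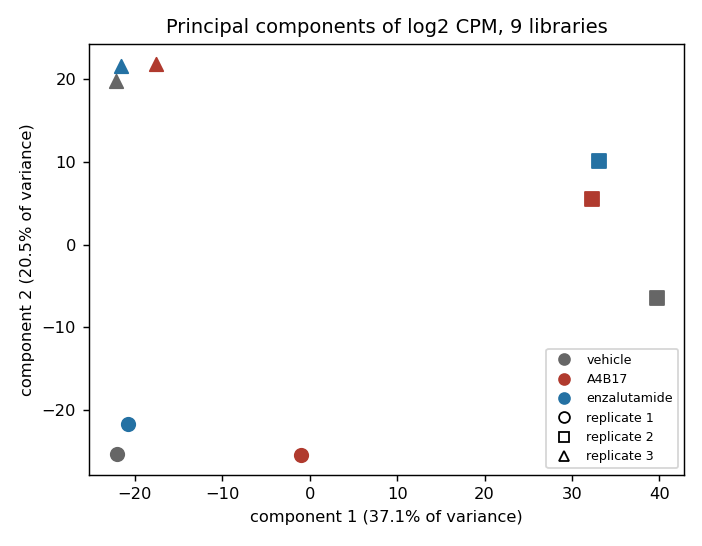
Principal components of the log2 CPM of all 9 libraries, with component 1 on the horizontal axis (37.1% of the variance) and component 2 on the vertical axis (20.5%). Colours mark the treatment and symbols the replicate number. Libraries with the same number mostly lie near each other. A4B17 library 1 lies apart on component 1, at -1.03 against -22.1 for vehicle library 1 and -20.8 for enzalutamide library 1.

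The first comparison asked which transcripts differ between cells given A4B17 and cells given vehicle. Of the 9 genes that rose, 6 belong to a fixed list of targets of NRF2, the transcription factor of the antioxidant response. AKR1C2, which encodes an aldo-keto reductase acting on steroids, rose from 1.34 ± 0.445 to 11.8 ± 5.20 CPM (counts scaled to a common library total; SD, n = 3). Its relative AKR1C3, which makes testosterone from androstenedione, rose from 7.32 ± 1.27 to 29.9 ± 5.65 CPM. OSGIN1, an oxidative stress-induced gene, rose from 73.8 ± 6.08 to 257 ± 79.0 CPM, and GCLM, the modifier subunit of the enzyme that limits glutathione synthesis, from 55.8 ± 9.40 to 164 ± 25.5.

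In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9 of the 14498 genes rose and 0 fell at an adjusted p below 0.05, and 976 genes lay below 0.05 without adjustment. The DESeq2 Wald test called 109 genes, 85 higher and 24 lower. The log2 fold change was 3.13 ± 0.36 (SE) for AKR1C2 (chromosome 10, 4987400 to 5018031, GRCh38), 2.26 ± 0.26 for CYP4F11, a fatty acid hydroxylase gene (chromosome 19, 15912367 to 15934867), and 2.03 ± 0.21 for AKR1C3 (chromosome 10, 5035354 to 5107686). It was 1.80 ± 0.22 for OSGIN1 (chromosome 16, 83948282 to 83966332), 1.55 ± 0.19 for GCLM (chromosome 1, 93885205 to 93909456) and 1.49 ± 0.18 for CLIP4 (chromosome 2, 29097705 to 29189643). These 6 genes had an edgeR adjusted p of 0.0167. TRIM16L (chromosome 17, 18697998 to 18736118) had a log2 fold change of 1.06 ± 0.14, SRXN1, the sulfiredoxin gene (chromosome 20, 646615 to 653370), 1.01 ± 0.13, and FECH, the ferrochelatase of heme synthesis (chromosome 18, 57548283 to 57586772), 0.98 ± 0.13, each with an edgeR adjusted p of 0.0189. All 9 genes were higher with A4B17 in 3 of 3 same-numbered pairs. AKR1C2, AKR1C3, CYP4F11 and TRIM16L have close paralogs, so reads may have been split between copies and their levels are uncertain.

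**Figure D2:**
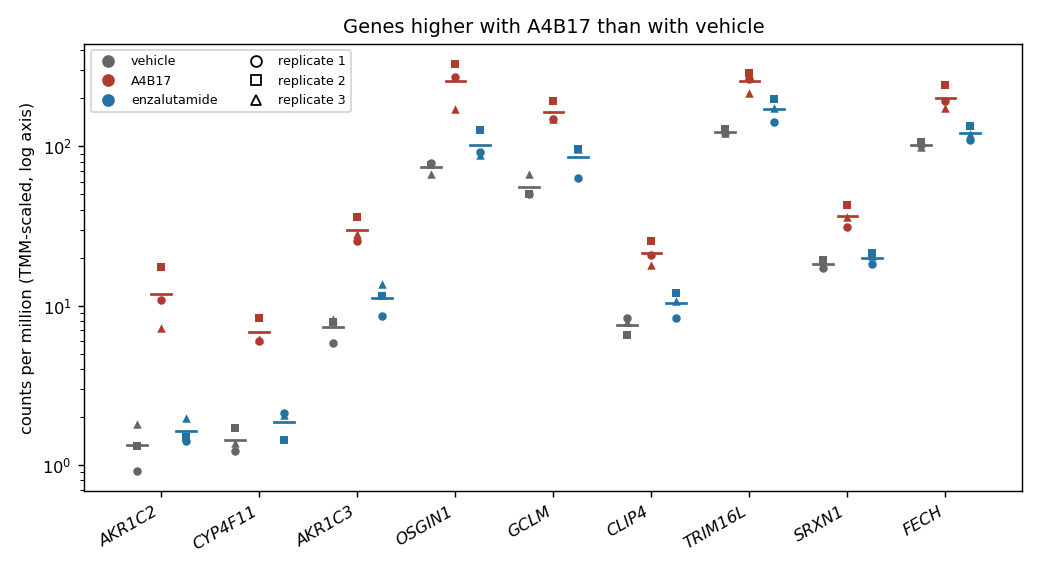
CPM, scaled by TMM factors, on a log axis for the 9 genes that rose with A4B17. Each symbol is 1 library, shaped by replicate number, and each bar is the mean of the 3 libraries of a treatment. For each gene the 3 A4B17 libraries lie above the 3 vehicle libraries.

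With the replicate number as a block, edgeR called 614 genes, 390 higher and 224 lower with A4B17, including all 9 above. Without composition scaling the blocked split was 270 higher and 266 lower. Among genes within the naming rule (protein-coding, a mean of at least 1 CPM and no overlap of the groups), those with the largest blocked rises included GDF15, a stress-induced cytokine gene (log2 fold change 3.18 ± 0.54, edgeR adjusted p = 0.0289), AKR1C1 (3.03 ± 0.45, 0.00111), HMOX1, the heme oxygenase that degrades heme (2.35 ± 0.23, 0.00436), and CBR3, a carbonyl reductase gene (2.15 ± 0.30, 0.0232). ABCC3, an export pump for conjugated organic anions, followed with 1.93 ± 0.23 and PANX2, a pannexin gene, with 1.76 ± 0.19. AKR1C1 shares the uncertainty of its paralogs. The largest blocked falls within the rule were in the readthrough gene P2RX5-TAX1BP3 (-1.48 ± 0.39), whose reads cannot be told from those of its component genes, RFTN1 (-1.31 ± 0.22), the histone gene HIST1H3H (-1.24 ± 0.31), which has near-identical copies, and ATP2A3, a calcium pump of the endoplasmic reticulum (-1.23 ± 0.16). CLCA2 (-1.06 ± 0.13), GABRQ (-0.99 ± 0.15), MOGAT2 (-0.99 ± 0.24), MAP2K6, a kinase upstream of p38 (-0.97 ± 0.16), KLLN (-0.97 ± 0.24) and the mucin gene MUC5AC (-0.94 ± 0.16) completed the 10 largest falls within the rule. Without the block, the edgeR adjusted p of these genes ranged upward from 0.0568, for PANX2.

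The count changed with single libraries, while the fold changes moved less. Over 20 alternative settings the log2 fold change was 2.72 to 3.40 for AKR1C2, 1.85 to 2.13 for AKR1C3 and 0.82 to 1.08 for FECH. Without the block, edgeR called 0 genes without vehicle library 1, vehicle library 2, A4B17 library 1 or A4B17 library 2, 3 genes without vehicle library 3, 30 without A4B17 library 3 and 14 without enzalutamide library 1. With the block, it called 363 without vehicle library 1, 261 without vehicle library 3, 359, 334 and 371 without A4B17 libraries 1, 2 and 3, 136 without all libraries numbered 1 and 210 without all those numbered 3.

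Of 24 tested NRF2 targets, 6 rose over all genes and 20 did when adjusted over the list alone, with a median log2 fold change of 1.14. With the block, 20 rose over all genes. The list stood above the other genes in camera (adjusted p = 6.1e-44), with adjusted p = 0.0719 with an estimated correlation, and fry gave an adjusted p of 0.00931. With the block, camera with an estimated correlation gave an adjusted p of 0.286, and fry gave 0.0139. Mean log2 levels of the list in same-numbered pairs were higher with A4B17 by 1.29, 1.45 and 0.93. NQO1, a quinone reductase gene shared with the aryl hydrocarbon receptor list, went from 1546 ± 139 to 3393 ± 771 CPM (SD, n = 3; blocked log2 fold change 1.11 ± 0.10).

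Targets of ATF4, the transcription factor of the integrated stress response, also stood higher (median log2 fold change 0.42, camera adjusted p = 2.9e-13, adjusted p = 0.190 with an estimated correlation). Of 23 tested members, 0 rose over all genes, 13 rose when adjusted over the list alone, and 14 rose over all genes with the block. The cystine transporter gene SLC7A11, also on the NRF2 list, had a blocked log2 fold change of 1.62 ± 0.21, the glutathione-degrading enzyme gene CHAC1 1.03 ± 0.14, DDIT3, which encodes the stress factor CHOP, 0.93 ± 0.16, and SLC3A2 0.51 ± 0.09. Of 9 tested aryl hydrocarbon receptor targets, 0 rose over all genes, 5 rose when adjusted over the list alone and 3 rose with the block (median 0.41, camera adjusted p = 1.9e-06, adjusted p = 0.190 with an estimated correlation). Those 3 were NQO1, also on the NRF2 list, SLC7A5, also on the ATF4 list (blocked log2 fold change 0.42 ± 0.08), and the monooxygenase gene CYP1A1 (0.60 ± 0.12).

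Replication genes of S phase stood lower with A4B17 (30 tested, median log2 fold change -0.20, camera adjusted p = 1.4e-05, adjusted p = 0.685 with an estimated correlation). None of the 30 fell over all genes or over the list alone without the block. With the block 4 fell, namely MCM6 (-0.34 ± 0.07) and MCM3 (-0.30 ± 0.07) of the replicative helicase, UHRF1 (-0.30 ± 0.08) and TK1. Endoplasmic reticulum chaperone genes stood higher (18 tested, median 0.12, camera adjusted p = 0.0175, adjusted p = 0.685 with an estimated correlation); 0 rose without the block and 3 with it, HSP90B1 (0.35 ± 0.06), DNAJB11 (0.39 ± 0.07) and MANF. Cholesterol synthesis genes stood higher (25 tested, median 0.08, camera adjusted p = 0.0295, adjusted p = 0.840 with an estimated correlation), with CYP51A1 the 1 member that rose with the block (0.52 ± 0.10). Cytosolic ribosomal protein genes had a median of 0.06 (30 tested, camera adjusted p = 0.0295, adjusted p = 0.843 with an estimated correlation), and 0 members rose in either fit; without vehicle library 3 the median was -0.0076 (camera adjusted p = 0.953). Interferon response genes stood lower (15 tested, median -0.27, camera adjusted p = 0.0175, adjusted p = 0.201 with an estimated correlation), with 1 member, OAS1, below threshold in the blocked fit (-0.82 ± 0.21). With the block, camera also placed heat shock genes higher (adjusted p = 0.0129, adjusted p = 0.740 with an estimated correlation), fatty acid synthesis genes lower (0.0183, adjusted p = 0.672 with an estimated correlation) and immediate early genes higher (0.0487, adjusted p = 0.361 with an estimated correlation).

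With the block and adjusted over the list alone, more members of several lists passed than over all genes. Among NRF2 targets 23 rose, among ATF4 targets 17 rose and 1 fell, among endoplasmic reticulum chaperone genes 7 rose and 1 fell, and 9 S phase genes fell. Aryl hydrocarbon receptor targets had 5 that rose, and 3 androgen-repressed genes fell, AR, UGT2B11 and UGT2B15. Luminal markers had 2 that rose and 3 that fell, and basal markers 4 that rose and 1 that fell.

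Several of these list calls ended when 1 library was left out, given here with the camera adjusted p and the list median without it. The S phase list lost its call without vehicle library 2 (0.485, -0.05). Cholesterol synthesis lost it without vehicle library 2 (0.0656, 0.12), vehicle library 3 (0.427, 0.03), A4B17 library 1 (0.405, -0.0110) or A4B17 library 2 (0.130, 0.07). Ribosomal proteins lost it without vehicle library 1 (0.682, 0.00992), vehicle library 3 (0.953, -0.00762), A4B17 library 1 (0.706, 0.00635) or A4B17 library 2 (0.132, 0.06). Endoplasmic reticulum chaperones lost it without vehicle library 3 (0.295, 0.11), A4B17 library 1 (0.232, 0.10) or A4B17 library 2 (0.0741, 0.10). The interferon list lost it without vehicle library 1 (0.0560, -0.21), vehicle library 2 (0.0993, -0.22), A4B17 library 1 (0.0503, -0.34) or A4B17 library 2 (0.0544, -0.21). Androgen-repressed genes lost it without vehicle library 1 (0.114, -0.21), vehicle library 2 (0.0656, -0.41), A4B17 library 1 (0.0503, -0.55), A4B17 library 2 (0.0994, -0.28), A4B17 library 3 (0.126, -0.13) or enzalutamide library 1 (0.0618, -0.31). The leukocyte and endothelial markers lost it without vehicle library 2 (0.0656, -0.99) or A4B17 library 1 (0.121, -1.07). Same-numbered pairs went both ways for ribosomal proteins (log2 differences of 0.35, -0.22 and 0.13) and the interferon list (-0.44, -0.49 and 0.02).

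The transcripts of the compounds' named targets were measured in the same fits. BAG1 (chromosome 9, 33247820 to 33264720) stood at 74.1 ± 7.997 CPM with vehicle, 69.3 ± 5.34 with A4B17 and 62.3 ± 4.03 with enzalutamide (SD, n = 3), and its log2 fold change with A4B17 was -0.10 ± 0.11 (edgeR adjusted p = 0.983). None of the 6 BAG family genes passed in either fit. AR (chromosome X, 67544032 to 67730619) stood at 101 ± 27.4 with vehicle and 78.7 ± 20.7 with A4B17, a log2 fold change of -0.36 ± 0.25 (edgeR adjusted p = 0.907) that became -0.35 ± 0.08 (0.0170) with the block. Of 31 tested androgen-induced genes, 0 passed over all genes or over the list alone, and with the block RHOU (0.24 ± 0.06) and ELL2 rose. Their median log2 fold change was -0.05 while camera gave the upward direction (adjusted p = 0.735). Of 5 tested androgen-repressed genes, AR among them, 0 fell without the block, and the list stood lower (median -0.36, camera adjusted p = 0.0225, adjusted p = 0.190 with an estimated correlation); UGT2B11 had a log2 fold change of -1.22 ± 0.40 and UGT2B15 of -0.38 ± 0.24, both in a family whose members share reads.

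**Figure D3:**
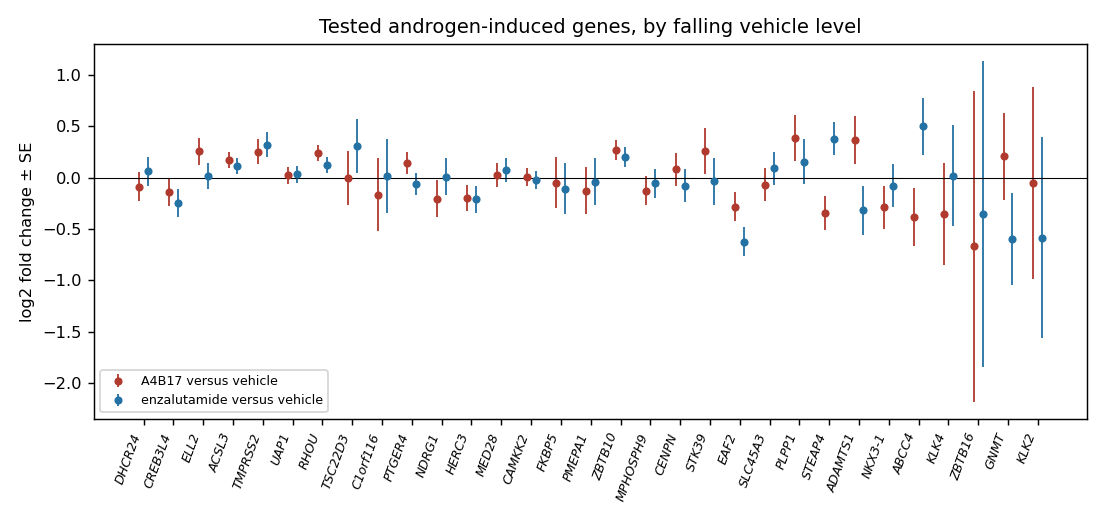
Log2 fold change ± SE of each tested androgen-induced gene against vehicle, for A4B17 and for enzalutamide, with genes ordered from the highest to the lowest vehicle level. Points scatter on both sides of 0, with medians of -0.05 for A4B17 and 0.01 for enzalutamide.

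Markers of other cell types were sparse. The leukocyte and endothelial list had 2 tested members and stood lower with A4B17 (camera adjusted p = 0.00162, adjusted p = 0.162 with an estimated correlation). CDH5, the cadherin of endothelial cells, had 4, 9 and 28 counts in the vehicle libraries, 0, 0 and 1 with A4B17 and 9, 17 and 11 with enzalutamide. VWF had 12, 17 and 9 counts with vehicle and 4, 5 and 7 with A4B17. Both fell when adjusted over the list alone, and CDH5 also fell over all genes with the block (edgeR adjusted p = 0.0113). Without the block 0 of 15 luminal, 0 of 10 basal, 0 of 3 neuroendocrine and 0 of 4 fibroblast and smooth muscle markers passed. With it, the luminal keratin gene KRT19 (-0.35 ± 0.09), PSCA (-0.44 ± 0.10) and AR fell, the basal marker KRT15 fell (-1.001 ± 0.07) while ITGA6 rose (0.54 ± 0.14), and SOX2 of the neuroendocrine list fell (-0.56 ± 0.14).

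The other leading members of these lists did not pass over all genes in either fit, and their log2 fold changes ± SE without the block were as follows. Androgen-induced genes had ZBTB10 (0.27 ± 0.10), ACSL3 (0.17 ± 0.08) and TMPRSS2 (0.25 ± 0.12), and the androgen-repressed CAMK2N1 had -0.26 ± 0.39. Of the BAG co-chaperones there were BAG6 (-0.21 ± 0.10), BAG2 (0.38 ± 0.20) and BAG3 (0.08 ± 0.13). Stress and metabolic lists had HERPUD1 (0.25 ± 0.12) and HYOU1 (0.17 ± 0.08) for protein folding, SQLE (0.25 ± 0.10), HMGCR (0.21 ± 0.11) and SC5D (0.21 ± 0.12) for sterol synthesis and TIPARP (0.68 ± 0.17) for the aryl hydrocarbon receptor. The S phase list had MCM7 (-0.29 ± 0.13) and CCNE1 (-0.33 ± 0.15), and the ribosomal proteins RPL4 (0.18 ± 0.11), RPL30 (0.15 ± 0.13), RPL10 (0.14 ± 0.14) and RPS14 (0.14 ± 0.14). Antiviral genes of the interferon list had OAS3 (-0.47 ± 0.22), DDX58 (-0.36 ± 0.19), CMPK2 (-0.56 ± 0.31) and IRF7 (-0.23 ± 0.13). Epithelial markers had EPCAM (0.21 ± 0.14), NGFR (1.31 ± 0.43) and LAMB3 (0.83 ± 0.45), neuroendocrine markers SYP (0.79 ± 0.44) and ENO2 (0.08 ± 0.18), and mesenchymal markers VIM (-0.60 ± 0.41), MYH11 (0.34 ± 0.57), TAGLN (-0.12 ± 0.52) and COL1A1 (0.06 ± 0.29). In the 15 lists not described here 0 members passed without the block; with it, 2 rose in the heat shock, G2/M, p53, immediate early and hypoxia lists each, 1 in the coregulator, ribosome biogenesis and pregnane X receptor lists each, while 2 coregulator genes, 1 hypoxia gene and 1 fatty acid gene fell.

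**Figure D4:**
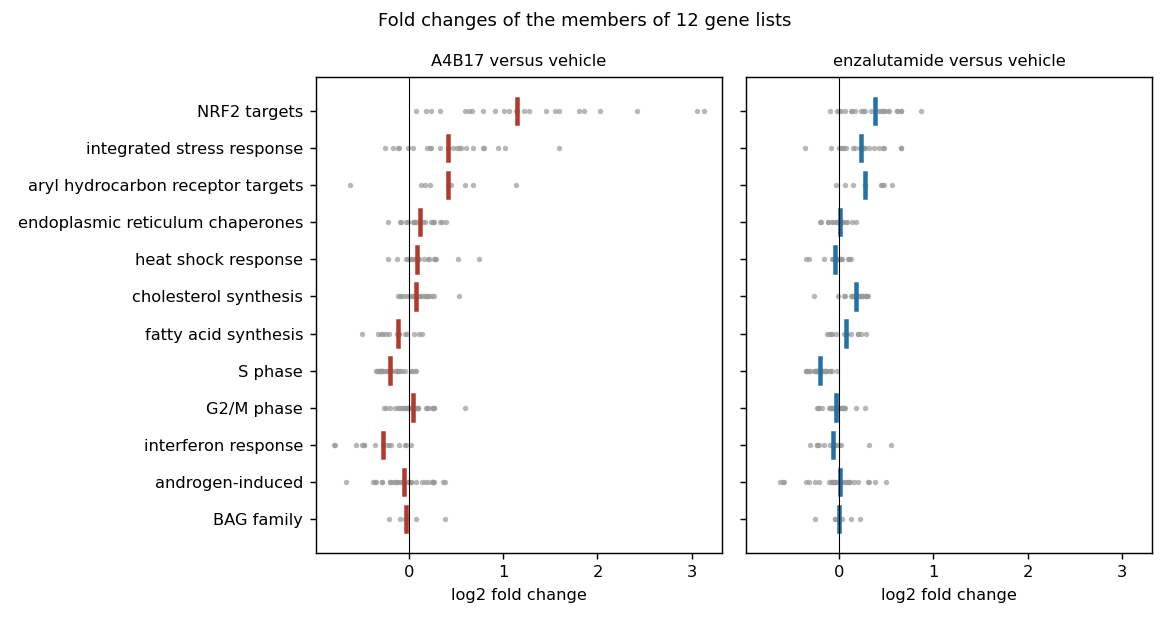
Log2 fold changes against vehicle of the tested members of selected gene lists, for A4B17 on the left and enzalutamide on the right. Grey points are genes and coloured bars are list medians; the NRF2 targets have medians of 1.14 with A4B17 and 0.38 with enzalutamide.

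The second comparison asked what enzalutamide changed against vehicle under the same androgen. Androgen-induced genes did not stand lower as a list. Their median log2 fold change was 0.01 and their mean -0.03 over 31 tested members, and the mean over 3 same-numbered pairs was -0.02 (95% interval -0.24 to 0.20). EAF2, an elongation factor gene, had a log2 fold change of -0.62 ± 0.14 and was the 1 member that fell when adjusted over the list alone; TMPRSS2, a membrane serine protease gene, had 0.32 ± 0.12. Neither passed over all genes, and camera gave an adjusted p of 0.907 for the list. With the block and adjusted over the list alone, EAF2 (-0.63 ± 0.13) and CREB3L4 (-0.25 ± 0.07) fell while TMPRSS2 (0.32 ± 0.08) and TSC22D3 (0.29 ± 0.08) rose, and the list median was -0.03. Of 40 listed genes 31 had enough counts to be tested, and KLK3, with 0 to 3 counts per library, did not. No group lacked androgen, so whether the listed genes respond to it in these cells was not measured. The result cannot tell failed antagonism from a list that does not respond to androgen here.

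Over all genes edgeR called 0 in this comparison, with 281 genes below an unadjusted p of 0.05, and DESeq2 called 0. With the block edgeR called 3, all higher with enzalutamide, and DESeq2 called 54, 37 higher and 17 lower. DHRS3, a retinaldehyde reductase gene (chromosome 1, 12567910 to 12617731), went from 21.2 ± 11.4 to 57.9 ± 15.8 CPM (SD, n = 3; blocked log2 fold change 1.53 ± 0.16, edgeR adjusted p = 0.0189). UBB, a polyubiquitin gene with sequence shared with other ubiquitin genes (chromosome 17, 16380798 to 16382745), had 0.60 ± 0.08 (0.0172). SFRP1, a secreted Wnt antagonist gene, had 0.65 ± 0.09 (edgeR adjusted p = 0.0203); its libraries overlapped between groups, so it lies outside the naming rule and was chosen after its values were seen. BAG1 had a log2 fold change of -0.25 ± 0.11 and AR of 0.09 ± 0.25, each with an edgeR adjusted p of 1.00; with the block, BAG1 (-0.25 ± 0.07) fell when adjusted over its list alone (0.0160) but not over all genes (0.254). In simulated data for this comparison the unblocked test recovered 17.9% of genes changed by 1.5-fold, 68.7% of those changed by 2-fold and 95.5% of those changed by 4-fold, and the blocked test recovered 74.6%, 95.5% and 100%. A gain from the block was built into these simulated data. With the block, the count was 0 without vehicle library 1 or vehicle library 2, 11 and 13 without A4B17 libraries 1 and 2, 1 without enzalutamide library 2 and 8 without all libraries numbered 2.

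As groups, 9 lists passed camera with enzalutamide, with 0 members called over all genes in either fit. Fry passed none (smallest adjusted p = 0.545). The S phase, NRF2, ATF4, aryl hydrocarbon receptor, cholesterol synthesis and androgen-repressed lists also passed camera the same way with A4B17. Both comparisons use the same vehicle libraries, so these matching shifts are not separate evidence for each compound. S phase genes stood lower (median -0.20 over 30 tested, camera adjusted p = 7.4e-11, adjusted p = 0.399 with an estimated correlation), among them MCM7 (-0.35 ± 0.13). Ribosome biogenesis and MYC targets stood lower (median -0.14 over 26, camera adjusted p = 4.3e-06, adjusted p = 0.399 with an estimated correlation), with NOP56 at -0.20 ± 0.09. NRF2 targets stood higher (median 0.38 over 24, camera adjusted p = 1.1e-09, adjusted p = 0.399 with an estimated correlation), with GCLM at 0.62 ± 0.18 and TRIM16L at 0.47 ± 0.14. Integrated stress response genes (median 0.24 over 23, camera adjusted p = 4.8e-07, adjusted p = 0.399 with an estimated correlation) and aryl hydrocarbon receptor targets (median 0.28 over 9, camera adjusted p = 2.9e-07, adjusted p = 0.358 with an estimated correlation) also stood higher, the latter with 2 members higher when adjusted over the list alone, TIPARP (0.56 ± 0.17) and CYP1A1 (0.44 ± 0.14). Cholesterol synthesis genes stood higher (median 0.18 over 25, camera adjusted p = 4.3e-06, adjusted p = 0.671 with an estimated correlation), with SQLE at 0.24 ± 0.10. Mitochondrially encoded transcripts stood higher (median 0.15 over 13, camera adjusted p = 0.0106, adjusted p = 0.722 with an estimated correlation), but without enzalutamide library 2, which held the largest mitochondrial share at 5.51% of counts, their median was 0.0013. Androgen-repressed genes stood lower (median -0.18 over 5, camera adjusted p = 0.0297, adjusted p = 0.358 with an estimated correlation), with UGT2B15 at -0.84 ± 0.25 and lower when adjusted over the list alone. Glucocorticoid receptor targets stood higher (median 0.17 over 15, camera adjusted p = 0.0330, adjusted p = 0.358 with an estimated correlation), and their median was 0.08 with the block. With the block, camera also placed nuclear-encoded oxidative phosphorylation genes lower (adjusted p = 0.0248, adjusted p = 0.875 with an estimated correlation) and AR and its coregulators higher (0.0453, adjusted p = 0.708 with an estimated correlation). Leaving out 1 library ended some camera calls, given with the adjusted p and the list median without it. Cholesterol synthesis lost its call without enzalutamide library 2 (0.261, 0.08), mitochondrially encoded transcripts without vehicle library 3 (0.0785, 0.19) or enzalutamide library 2 (0.942, 0.00126), and glucocorticoid receptor targets without vehicle library 1 (0.0780, 0.08), vehicle library 2 (0.0804, 0.12), vehicle library 3 (0.0783, 0.23), enzalutamide library 2 (0.165, 0.17) or enzalutamide library 3 (0.203, 0.04). Same-numbered pairs went both ways for cholesterol synthesis (0.12, 0.38 and -0.04) and for mitochondrially encoded transcripts (-0.12, 0.39 and 0.17). With the block and adjusted over the list alone, 12 NRF2 targets rose where 0 did without it, 5 aryl hydrocarbon receptor targets rose, 6 S phase genes fell, 4 ATF4 targets rose and 1 fell, 2 androgen-repressed genes fell and 1 glucocorticoid receptor target rose. The mean level of the NRF2 targets was higher with enzalutamide by 0.23, 0.41 and 0.34 (log2) in the 3 same-numbered pairs. None of the 6 BAG family genes and none of the tested luminal, basal, neuroendocrine, fibroblast, leukocyte or endothelial markers passed over all genes.

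The remaining leading members of these lists, none of which passed over all genes in either fit, had the following log2 fold changes ± SE. Replication and growth genes were UHRF1 (-0.35 ± 0.15), CCNE1 (-0.34 ± 0.15) and TYMS (-0.25 ± 0.13) in S phase, and SRM (-0.29 ± 0.14), MRTO4 (-0.27 ± 0.13) and BOP1 (-0.21 ± 0.11) in ribosome biogenesis. Stress genes were DDIT4 (0.66 ± 0.24), SLC7A11 (0.66 ± 0.26), ATF3 (0.43 ± 0.18) and CHAC1 (0.47 ± 0.21) of the ATF4 targets and AKR1C3 (0.61 ± 0.21) and TXNRD1 (0.53 ± 0.19) of the NRF2 targets. Xenobiotic and sterol genes were AHRR (0.48 ± 0.18) and NQO1 (0.46 ± 0.17), and CYP51A1 (0.28 ± 0.13), INSIG1 (0.29 ± 0.14) and HMGCS1 (0.29 ± 0.16). Steroid-responsive genes were STEAP4 (0.38 ± 0.16) and ZBTB10 (0.20 ± 0.10) for androgen induction, UGT2B11 (-0.98 ± 0.40) and CAMK2N1 (-0.18 ± 0.39) for androgen repression and CDKN1C (0.32 ± 0.15), CRISPLD2 (0.60 ± 0.31), BIRC3 (0.60 ± 0.36) and SGK1 (1.01 ± 0.60) for the glucocorticoid receptor. Respiratory chain transcripts of mitochondrial DNA were MT-ND5 (0.32 ± 0.17), MT-ND4 (0.28 ± 0.17), MT-ND4L (0.38 ± 0.24) and MT-CO1 (0.26 ± 0.17). BAG co-chaperones were BAG2 (0.23 ± 0.20), BAG3 (0.13 ± 0.13) and BAG6 (-0.04 ± 0.10). Epithelial markers were ACPP (-0.55 ± 0.25), PSCA (-0.26 ± 0.22) and STEAP2 (0.48 ± 0.46) of the luminal and NGFR (1.25 ± 0.43), KRT14 (-0.42 ± 0.22), LAMB3 (0.68 ± 0.46) and ITGA6 (0.21 ± 0.17) of the basal list. Other markers were ENO2 (0.16 ± 0.18), SOX2 (-0.23 ± 0.56) and SYP (0.01 ± 0.46) of the neuroendocrine, MYH11 (0.42 ± 0.57), VIM (-0.10 ± 0.40), TAGLN (-0.09 ± 0.52) and COL1A1 (-0.04 ± 0.29) of the mesenchymal and VWF (-0.44 ± 0.49) and CDH5 (-0.05 ± 0.66) of the endothelial list. In the 15 lists not described here 0 members passed in either fit.

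The third comparison set A4B17 directly against enzalutamide. NRF2 targets stood higher with A4B17 in all 24 tested members, with a median log2 fold change of 0.71. Adjusted over the list alone, 19 rose, 0 rose over all genes without the block and 18 rose with it (camera adjusted p = 2.9e-38, adjusted p = 0.101 with an estimated correlation, fry adjusted p = 0.0259). AKR1C2 stood at 11.8 ± 5.20 CPM with A4B17 and 1.63 ± 0.289 with enzalutamide (SD, n = 3), and AKR1C3 at 29.9 ± 5.65 and 11.2 ± 2.505. DHRS3 stood lower with A4B17, at 19.9 ± 10.9 CPM.

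Over all genes edgeR called 0 between the compounds (622 below an unadjusted p of 0.05, smallest adjusted p = 0.114), and DESeq2 called 33. With the block edgeR called 260 genes, 136 higher and 124 lower with A4B17; without composition scaling the blocked split was 92 higher and 121 lower. The largest blocked rises within the naming rule were AKR1C2 (2.80 ± 0.30), AKR1C1 (2.59 ± 0.43), CYP4F11 (1.85 ± 0.23), HMOX1 (1.54 ± 0.22), ABCC3 (1.502 ± 0.22), AKR1C3 (1.42 ± 0.12), OSGIN1 (1.30 ± 0.13), CYP4F3, a paralog of CYP4F11 (1.24 ± 0.24), GPAT3, which acylates glycerol 3-phosphate (1.15 ± 0.18), and CLIP4 (1.04 ± 0.15). The largest blocked falls within the rule were DHRS3 (-1.63 ± 0.16), HIST1H3H (-1.39 ± 0.30), NAV2 (-1.05 ± 0.21), MAP2K6 (-1.04 ± 0.16), ATP2A3 (-0.97 ± 0.17), TNFSF15 (-0.91 ± 0.15), LMO2 (-0.89 ± 0.18), the clock-linked repressor gene BHLHE40 (-0.86 ± 0.08), HIC1 (-0.84 ± 0.20) and LRP1 (-0.83 ± 0.20). AR was lower with A4B17 than with enzalutamide by edgeR with the block (-0.45 ± 0.08, adjusted p = 0.00723), and without it the value was -0.45 ± 0.25 (0.9998). BAG1 had 0.15 ± 0.11 and did not pass. The unblocked count was 2 without A4B17 library 3, and the blocked count was 691 without vehicle library 2, 150 without vehicle library 3, 94, 142 and 150 without A4B17 libraries 1, 2 and 3, 25 and 32 without enzalutamide libraries 1 and 2, 9 without all libraries numbered 1 and 122 without all those numbered 3.

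Among the other lists, integrated stress response genes stood higher with A4B17 (median 0.17 over 23, camera adjusted p = 4.0e-06, adjusted p = 0.480 with an estimated correlation), with 3 members higher and 1 lower in the blocked fit, among them CHAC1 at 0.58 ± 0.13, TRIB3 at 0.33 ± 0.08 and DDIT4 at -0.78 ± 0.13. Fatty acid synthesis genes stood lower (median -0.17 over 14, camera adjusted p = 0.00302, adjusted p = 0.480 with an estimated correlation), and ELOVL6 (-0.59 ± 0.13), FASN, the fatty acid synthase (-0.49 ± 0.12), and SREBF1, their transcriptional activator (-0.37 ± 0.07), fell with the block. Heat shock genes (median 0.13 over 21, camera adjusted p = 0.00530, adjusted p = 0.747 with an estimated correlation) and endoplasmic reticulum chaperone genes (median 0.17 over 18, camera adjusted p = 0.00530, adjusted p = 0.710 with an estimated correlation) stood higher, each with 2 members called in the blocked fit, DNAJB4 (0.59 ± 0.11) and HSPH1 (0.32 ± 0.07) in the first and HSP90B1 (0.31 ± 0.06) and DNAJB11 (0.39 ± 0.07) in the second. Cytosolic ribosomal protein genes (median 0.10, camera adjusted p = 0.00809, adjusted p = 0.776 with an estimated correlation) and G2/M genes (median 0.08, camera adjusted p = 0.0314, adjusted p = 0.747 with an estimated correlation) stood higher, with 0 and 1 members called with the block, the latter CCNB1, the cyclin B1 gene (0.29 ± 0.07). Interferon response genes (median -0.24, camera adjusted p = 0.0440, adjusted p = 0.480 with an estimated correlation), AR and its coregulators (median -0.08, camera adjusted p = 0.0475, adjusted p = 0.747 with an estimated correlation) and the 2 tested leukocyte and endothelial markers (camera adjusted p = 0.00307, adjusted p = 0.185 with an estimated correlation) stood lower. OAS1, NCOA3 and AR, and CDH5 were their members called with the block. Of 31 androgen-induced genes, STEAP4 was called, lower with A4B17, with the block (-0.73 ± 0.15). Camera calls lost with 1 library left out are given with the adjusted p and the list median without it. Heat shock was lost without A4B17 library 1 (0.206, 0.09), A4B17 library 2 (0.209, 0.07) or enzalutamide library 3 (0.246, 0.07), endoplasmic reticulum chaperones without A4B17 library 1 (0.104, 0.11) or enzalutamide library 3 (0.317, 0.09), and G2/M without A4B17 library 2 (0.543, 0.05) or enzalutamide library 3 (0.480, 0.03). Ribosomal proteins were lost without A4B17 library 1 (0.541, 0.04) or enzalutamide library 1 (0.202, 0.07), coregulators without vehicle library 1 (0.0521, -0.08), A4B17 library 1 (0.671, -0.00138), enzalutamide library 1 (0.0714, -0.10) or enzalutamide library 3 (0.317, -0.04), and interferon without A4B17 library 1 (0.0634, -0.23), A4B17 library 2 (0.0964, -0.17), A4B17 library 3 (0.133, -0.28) or enzalutamide library 2 (0.257, -0.17). Fatty acid synthesis was lost without enzalutamide library 1 (0.0603, -0.14), and leukocyte and endothelial markers without A4B17 library 1 (0.0615, -0.69). Same-numbered pairs went both ways for heat shock (0.33, 0.14 and -0.01), ATF4 targets (0.44, 0.20 and -0.0022) and ribosomal proteins (0.32, 0.06 and -0.08). With the block and adjusted over the list alone, 23 NRF2 targets, 11 ATF4 targets, 8 endoplasmic reticulum chaperone genes, 5 heat shock genes and 2 G2/M genes rose, while 1 ATF4 target, 1 heat shock gene, 4 fatty acid synthesis genes and 3 coregulators fell. Androgen-induced genes had 2 that rose and 3 that fell in that setting, androgen-repressed genes 1 and 1, and luminal markers 1 and 3.

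Leading members that did not pass over all genes in either fit had the following log2 fold changes ± SE between the compounds. Stress lists had SLC7A11 (0.94 ± 0.25) and DDIT3 (0.62 ± 0.19) for ATF4, HSPA1B (-0.24 ± 0.11) and CHORDC1 (0.25 ± 0.11) for heat shock and HYOU1 (0.24 ± 0.08) and DNAJB9 (0.29 ± 0.17) for protein folding. Growth lists had CDC20 (0.27 ± 0.11), TOP2A (-0.19 ± 0.09) and NUF2 (0.21 ± 0.10) for mitosis and RPL30 (0.18 ± 0.13), RPS14 (0.15 ± 0.14), RPL3 (0.14 ± 0.14) and RPL27A (0.16 ± 0.16) for ribosomal proteins. Lipid and antiviral lists had ACLY (-0.20 ± 0.10) and SCD (-0.42 ± 0.26), and DDX58 (-0.30 ± 0.20), IFIT1 (-0.58 ± 0.39) and IRF7 (-0.18 ± 0.13). Androgen-linked genes had ABCC4 (-0.88 ± 0.28), ADAMTS1 (0.68 ± 0.23) and EAF2 (0.34 ± 0.14) for induction, UGT2B15 (0.46 ± 0.25), UGT2B11 (-0.24 ± 0.42) and CAMK2N1 (-0.08 ± 0.39) for repression and FOXA1 (-0.26 ± 0.11), NR3C1 (0.23 ± 0.11) and GATA2 (-0.17 ± 0.10) among the coregulators. BAG co-chaperones had BAG6 (-0.16 ± 0.10), BAG2 (0.16 ± 0.20) and BAG4 (-0.05 ± 0.10). Epithelial markers had KRT19 (-0.29 ± 0.14), EPCAM (0.25 ± 0.14) and MSMB (-1.20 ± 0.82) in the luminal and ITGA6 (0.32 ± 0.17), TRIM29 (0.52 ± 0.56) and KRT5 (0.29 ± 0.66) in the basal list, where KRT15 fell with the block. Other markers had SYP (0.78 ± 0.44), SOX2 (-0.35 ± 0.57) and ENO2 (-0.08 ± 0.18) in the neuroendocrine, VIM (-0.50 ± 0.41), COL1A1 (0.10 ± 0.29), MYH11 (-0.08 ± 0.56) and TAGLN (-0.03 ± 0.52) in the mesenchymal and VWF (-0.80 ± 0.53) in the endothelial list. In the 14 lists not described here 0 members passed without the block; with it, 2 p53 targets fell and 1 gene rose in each of the aryl hydrocarbon receptor, hypoxia and pregnane X receptor lists.

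The compounds were also compared gene by gene against the shared vehicle libraries. No gene changed the same way with both compounds in the unblocked edgeR test, since 0 passed with enzalutamide, and 0 changed in opposite directions; 1 changed the same way with the block, UBB, which went from 173 ± 17.4 CPM with vehicle to 266 ± 38.1 with A4B17 and 264 ± 46.4 with enzalutamide (SD, n = 3). Simulated unchanged groups against the same vehicle libraries gave a mean of 0.175 such genes in 40 draws with the block, and independent lists would give 0.0807. With 3 vehicle libraries the controls could not be split, and part of the excess of this count may come from sharing them. Across genes, which are not independent replicates, the correlation of both sets of log2 fold changes was 0.493, against 0.496 ± 0.014 (SD) in the simulated draws. Their covariance was 0.0382 against a simulated 0.0254 ± 0.00106 (SD), an excess of 0.0128. The simulated genes were drawn independently, while real genes vary together within libraries, so this SD may be too small. The excess can therefore not be read as a shared effect of both compounds. The same sign was seen in 67.2% of genes, against 66.5% in the simulated draws.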

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

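The alternatives run within the blocked fit, and DESeq2 and limma-voom with the block, were chosen after the data were seen. Counts of changed genes moved by more than 1.5 times under many settings; the cause was not tested, except that stricter thresholds lower a count by construction. For A4B17 against vehicle the count of 9 became 16 with library totals only, 109 with DESeq2, 173 with no filter, 15 in the fit of only the compared groups, 614 with the replicate block, 769 with the block and a GC and length correction, 530 with DESeq2 and the block, 607 with limma-voom and the block, and 0 at an adjusted p below 0.01. For enzalutamide against vehicle the count of 0 became 23 with no filter, 3 with the block, 4 with the block and GC and length correction, 54 with DESeq2 and the block and 4 with limma-voom and the block. For A4B17 against enzalutamide the count of 0 became 33 with DESeq2, 88 with no filter, 260 with the block, 353 with the block and GC and length correction, 305 with DESeq2 and the block and 241 with limma-voom and the block. Within the blocked fit, 614 became 944 with no filter, 234 with only the compared groups, 9 with no block, 62 at a log2 fold change of at least 1 and 211 at an adjusted p below 0.01. The blocked 3 became 5 with DESeq2 size factors, 6 with library totals, 54 with DESeq2, 196 with no filter, 14 with only the compared groups, 0 with no block, 1 at a log2 fold change of at least 1 and 0 at an adjusted p below 0.01. The blocked 260 became 589, 392, 0, 21 and 68 with no filter, only the compared groups, no block, a log2 fold change of at least 1 and an adjusted p below 0.01.

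Leaving out libraries gave 0 to 30, 0 to 0 and 0 to 2 genes in the 3 comparisons without the block and 136 to 646, 0 to 13 and 9 to 691 with it. Genes changed the same way by both compounds numbered 14 with no filter, 1 with the block, 1 with the block and GC and length correction, 15 with DESeq2 and the block and 2 with limma-voom and the block, and 0 to 0 with libraries left out. The correlation of both sets of fold changes ranged from 0.376 to 0.645 over left-out libraries. Lists past camera numbered 10, 9 and 10; with an estimated correlation 0, 0 and 0, with fry 2, 0 and 2, and with libraries left out 4 to 13, 9 to 12 and 4 to 11. With the block camera passed 13, 11 and 10 lists. For A4B17 against vehicle, fry with the block also passed androgen-repressed genes (down, adjusted p = 0.0228), endoplasmic reticulum chaperones (up, 0.0252) and immediate early genes (up, 0.0417), each with camera adjusted p = 0.361 with an estimated correlation. It also passed pregnane X receptor targets (up, 0.0252), with 3 tested members and a median of -0.08 with the block; camera with the block gave 0.340, and adjusted p = 0.665 with an estimated correlation. For A4B17 against enzalutamide it also passed endoplasmic reticulum chaperones (up, 0.0308) and G2/M genes (up, 0.0445), each with camera adjusted p = 0.364 with an estimated correlation. There it also passed the 3 pregnane X receptor targets (up, 0.0445; median 0.06), with camera at 0.222 and adjusted p = 0.641 with an estimated correlation. Of 223 gene values 24 changed sign in some setting, 0 of them with a call, and of 49 list medians 19 did, all with 1 library left out. Among lists that passed camera, the median changed sign for cholesterol synthesis with A4B17 (-0.0110 without A4B17 library 1) and for ribosomal proteins with A4B17, which ranged from -0.0076 (without vehicle library 3) to 0.262, and camera turned to the other direction for the mitochondrially encoded transcripts with enzalutamide, with medians from 0.0013 (without enzalutamide library 2) to 0.286. Each of the 9 genes called for A4B17 kept its sign in 20 settings, with AKR1C2 between 2.72 and 3.40 and adjusted p up to 0.149.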

Other observations

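The tests of swapped labels, of AR level, of luminal markers and of the unblocked splits, and the count of genes detected after thinning, were chosen after the results were seen; the bound for AR was also moved to the median after its value was known. The test of sequence shared by KLK2 and KLK3 replaced an earlier one, on the levels of other androgen-induced genes, that could not decide the matter.

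Several transcripts set the baseline of this culture. CYP1A1, the classic target of the aryl hydrocarbon receptor, had a mean of 7398 CPM over the 9 libraries and ranked 4 among tested genes, while CYP1B1 stood at 379. KRT19 stood at 4383, KRT8 at 1911, CDH1 at 544 and TMPRSS2 at 183 CPM. NKX3-1, an androgen-induced prostate transcription factor, stood at 4.45 and HOXB13 at 1.65.

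Many genes differed by replicate number. In the libraries numbered 3, ZBTB16, which androgens and glucocorticoids induce, was higher (log2 difference 4.26 ± 0.39). All 4 tested members of the metallothionein list, including the zinc transporter gene SLC30A1, were higher there (median 1.33). The trefoil factor gene TFF1 (-2.49 ± 0.19), TFF3 (-2.16 ± 0.10) and CGA (-2.56 ± 0.11) were lower. In those libraries 19 of 25 oxidative phosphorylation genes, 15 of 25 cholesterol synthesis genes and 13 of 21 heat shock genes were lower. As lists these had camera adjusted p of 1.0e-07, 3.3e-07 and 7.1e-07, and adjusted p = 0.578, 0.578 and 0.577 with an estimated correlation. The metallothionein list had camera adjusted p = 7.0e-04, and adjusted p = 0.376 with an estimated correlation. In the libraries numbered 2, 18 of 30 S phase genes were higher (camera adjusted p = 3.8e-07, adjusted p = 0.520 with an estimated correlation), and MSH5 (-3.07 ± 0.22), SEC31B (-2.47 ± 0.20) and EIF4A1 (-2.23 ± 0.17) were lower. Genes outside the protein-coding class, with mitochondrial genes left out, took 1.16% to 1.25% of counts there against 1.41% to 1.51% elsewhere. EIF4A1 stood at only 1.53 to 9.36 CPM over all libraries. Overlapping readthrough genes may take reads from EIF4A1 and MSH5, so their levels and differences are uncertain. In all, 5190 genes (35.8%) differed between numbers in edgeR; the genes named here were chosen after their values were seen.

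The first pattern weighed is that libraries with the same number deviate together, with a lowest correlation of 0.379. Thinning to equal totals left 0.364, but totals were already close, so this says little about unequal totals. A correction for GC content and gene length left 0.370, and leaving out the 100 most abundant genes 0.380. These values argue against GC or length trends and a few abundant genes as the whole cause. Thinning did not equalise the genes detected, which stayed at 19784 to 19865 in the libraries numbered 2 against 21387 to 22670 in the others, so a difference in library complexity stays open. A shared culture, day or library batch was not tested, since the labels give none, and no biological explanation was tested.

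The second pattern is the higher level of NRF2 targets with A4B17, with a median log2 fold change of 1.14. The median was 1.13 after thinning to equal totals. Totals were already close (15834105 to 18623197) and fold changes were scaled for them, so thinning could hardly move the median and decides nothing about totals. After the GC and length correction with the block the median was 1.12, which argues against those trends. The smallest gap of an A4B17 library over its same-numbered libraries was 0.591 on the log2 scale, against a spread of 0.235, which argues against swapped labels of 1 or 2 A4B17 libraries. An exchange of all 3 A4B17 labels with another group would give the same gaps and stays open. No biological explanation was tested.

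The third pattern is the near absence of KLK3 and KLK2, the prostate-specific antigen gene and its neighbour, in cells given androgen. KLK3 had 0 to 3 counts and KLK2 2 to 18 per library, and 8 of the 37 other androgen-induced genes outside the kallikrein family were also under 1 CPM. AR lay at percentile 75.6 or higher of tested genes in each library, at 66.7 to 136 CPM, so its transcript was present. CPM is not corrected for gene length, and longer transcripts gather more reads. The percentile can therefore not decide whether the AR transcript is low against other genes. At most 0.415% of the 50-base stretches of either kallikrein transcript occur in another gene, which argues against reads lost to shared sequence. A culture that lost luminal markers or another line cannot be told apart from silent targets. Of 6 luminal markers, 5 lay above the median, namely KRT8, KRT18, KRT19, EPCAM and CDH1. Epithelial cells of other organs also express these 5, so their level cannot decide which line this is. HOXB13 did not lie above the median and had a mean of 1.65 CPM. For the androgen-induced list with enzalutamide, the lower end of the 95% interval of the mean was -0.237, which argues against a mean fall of 0.5 or more hidden by the spread. Whether the list responds to androgen in these cells stays open, since no group lacked androgen.

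Other splits of the 6 libraries were too few for a share under 0.05. For A4B17 against vehicle, 1 of 10 splits gave as many genes as the real 9 (highest other, 1), and with the block 1 of 4 splits that part all pairs gave the real 614 (highest other, 0). For enzalutamide against vehicle, 10 of 10 splits gave at least the real 0 (highest other, 0), and with the block 1 of 4 gave 3 (highest other, 0). For A4B17 against enzalutamide, 10 of 10 gave at least the real 0 (highest other, 0), and with the block 1 of 4 gave 260 (highest other, 0).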
